A study of Mus musculus with 4 samples.

How the data were processed

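Total RNA from 4 mouse samples was labelled with biotin and hybridised to Affymetrix mouse expression arrays, 1 array per sample. The labels give 3 leukemias and 1 normal bone marrow. Each leukemia had its own immunophenotype, so every group held 1 array. The mixed lineage leukemia carried both fusions, AF4-MLL and MLL-AF4. The proB acute lymphoblastic leukemia (proB ALL) and the biphenotypic acute leukemia of B and T type (B/T BAL) carried AF4-MLL alone. The last group was normal bone marrow. Per the labels, the leukemic cells came from the marrow of diseased mice and were typed by flow cytometry but not sorted.

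The deposited values were intensity values, 1 signal per probe set on a linear scale. The signals were made with MAS5, per the submitters' processing notes. Its version and settings are not given in the sources used here. The values themselves showed a trimmed mean of 1000 on each of the 4 arrays after removal of 2% of probe sets from each end, so the arrays share 1 global scale. MAS5 detection calls were not used here. Each array held 45101 probe sets. The 64 control probe sets were left out of all gene comparisons and used for quality values alone. Of the remaining 45037 probe sets, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were unnamed in the annotation used here. Probe sets with several genes or none were left out. No symbol differed after matching through gene identifiers to the RefSeq gene table, which held 34754 of the 34945 probe sets.

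Signals were analysed as log2(signal + 51.4), where 51.4 is the 25th percentile of all signals over the 4 arrays. Differences on this scale understate the change of dim genes. The median of all signals, 189, served as the floor. Each of 18193 genes was represented by its probe set with the highest mean log2 value, which also gives the signals in the text unless another probe set is named, and the 14012 genes whose representative exceeded the floor on at least 1 array were tested. Among 6382 genes with at least 2 measured probe sets, 94 had probe sets that differed at least 2-fold in opposite directions between the leukemias and normal marrow. A fold with the dimmer side at or below the floor was computed with that side at the floor and is given as "at least". 

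Leukemia was compared with normal marrow with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), 3 arrays against 1. The residual spread came from the 3 leukemias, with 2 degrees of freedom, and the lone normal array was assumed to vary like them. The leukemia with both fusions was compared with the 2 leukemias with AF4-MLL alone in the same way, with 1 residual degree of freedom from the difference between proB ALL and B/T BAL. The samples came from separate leukemias, so limma's p-values measure the spread between leukemias of different immunophenotype and not between replicates. Adjusted p-values are Benjamini-Hochberg values at a threshold of 0.05. Single arrays were compared without a test, by counting genes that differed at least 2-fold.

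Before the data were examined, 31 gene lists were fixed for cell types of the marrow, leukemia genes, the cell cycle, metabolism, stress and control genes. Of their 571 distinct genes, 60 had no probe set with a single gene symbol and were not analysed here. Lists were tested between leukemia and normal marrow with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. With an estimated correlation, camera also counts only the residual degrees of freedom of the fit, 2 here and 1 for both fusions against AF4-MLL alone. Lists could hardly pass with so few, so a list that fails there is not shown to fail through correlated genes. The early B-cell list had an estimated correlation of -0.03, below the preset value, and still passed only at the preset value. It was the exception among the lists that passed between leukemia and normal marrow. The others had estimated correlations above the preset value, from 0.04 for macrophage genes to 0.94 for late neutrophil genes. For those lists camera at the preset value may overstate the evidence. For single arrays each list's median log2 difference is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these arrays and is not a test of the conditions.

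Genes are named by a rule fixed before the data were examined: the 12 highest and 12 lowest of leukemia against normal marrow, ranked by the smallest of the 3 differences and not by a passed test because none passed, for each leukemia the 8 genes above and the 4 genes below all other 3 arrays, up to 4 genes of each list with the largest difference over the leukemias or on the array described, a fixed set of lineage, MLL and sex-linked genes, and the control probe sets of Actb and Gapdh. Genes outside this rule are said to be so where they are named.

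The tests were tried on simulated data made from the real gene means and the fitted distribution of variances, with 10 draws of 200 changed genes among 14012. In the comparison of leukemia with normal marrow, limma recovered 0% of genes changed by 2 on the log2 scale, 6.21% of those changed by 4 and 32.6% of those changed by 6, with 1.6 unchanged genes called per draw. In the comparison of both fusions with AF4-MLL alone, it recovered 0%, 5.46% and 20.9%, with 3.4 unchanged genes called per draw.

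The alternatives were quantile normalization, scaling to the 75th percentile, other pseudocounts, other filters, the mean over probe sets, leaving out probe sets whose identifiers mark possible cross-hybridisation (_x_at and _s_at), eBayes without a trend or with robust fitting, leaving out each leukemia, an estimated correlation in camera, random lists in place of camera, and a 4-fold threshold. Scaling to the 75th percentile moved the median difference of all tested genes between mixed lineage leukemia and normal marrow from 0.08 to 0.23 on the log2 scale, and that between mixed lineage leukemia and proB ALL from 0.18 to 0.42. That between mixed lineage leukemia and B/T BAL went from 0.08 to 0.27. Under quantile normalization the medians against normal marrow and against proB ALL were -0.01 and 0.05.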

Results

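The samples address how leukemias that arose from blood stem and precursor cells transduced with fusions of MLL (Kmt2a, a histone methyltransferase) and AF4 (Aff1, a transcription elongation factor) differ from normal bone marrow and from one another. RNA from 4 samples was hybridised to 1 mouse array each. The mixed lineage leukemia arose from cells with AF4-MLL and MLL-AF4, and the proB ALL and the B/T BAL arose from cells with AF4-MLL alone. The 4th sample was normal bone marrow. No group had a replicate, so a value of a single array has no replicate error. Cells were not sorted, and marker genes of resident marrow cells are therefore given beside the genes of each leukemia. On the mixed lineage array 57.4% of probe sets lay above the floor of 189, against 46.3% on the proB ALL array, 49.0% on the B/T BAL array and 47.2% on the normal array. The lowest signals were also higher on the mixed lineage array, where the 2nd percentile was 20.4 against 2.88, 3.97 and 3.52 on the proB ALL, B/T BAL and normal arrays. The 3' to 5' signal ratio of Actb, a measure of RNA and labelling quality, was 3.10 in mixed lineage leukemia, 2.47 in proB ALL, 4.72 in B/T BAL and 1.87 in normal marrow. The same ratio of Gapdh was 1.24, 1.28, 1.14 and 0.944. Xist, the X-inactivation RNA of female cells, had signals of 33134, 40587, 58725 and 23145 in mixed lineage leukemia, proB ALL, B/T BAL and normal marrow, while the Y-linked Kdm5d reached at most 200 and the Y-linked Uty at most 199, each on the mixed lineage array.

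Genes of red cell precursors were far lower in each of the 3 leukemias than in normal marrow. All 23 measured erythroid genes were at least 2-fold lower on each leukemia array, with median log2 differences of -5.37 in mixed lineage leukemia, -5.48 in proB ALL and -4.76 in B/T BAL. Alas2, the first enzyme of heme synthesis in red cells, had a signal of 39547 in normal marrow and of 263, 183 and 467 in mixed lineage leukemia, proB ALL and B/T BAL. Klf1, an erythroid transcription factor, had 21735 in normal marrow and 192, 104 and 165 in the leukemias. Car1 (carbonic anhydrase 1), Rhd (a Rh blood group protein), Ermap (an erythroid membrane protein) and Aqp1 (a water channel of red cells) were also among the 12 lowest genes, at least 105-fold, 106-fold, 118-fold and 101-fold lower over the 3 leukemias with signals below the floor counted at the floor. The erythroid list passed camera (adjusted p = 1.5e-72), though not with an estimated correlation (adjusted p = 0.201 with an estimated correlation). Adjusted over the list alone, 22 of its 23 genes were lower, against 0 over all genes tested.

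Several eosinophil and platelet genes were lower alongside. Epx and Prg3, proteins of eosinophil granules, had signals of 25742 and 11783 in normal marrow and lay at or below the floor in each leukemia, at least 136-fold and at least 62.5-fold lower. Prg2, another eosinophil granule protein, had 43661 in normal marrow and 2186, 248 and 267 in mixed lineage leukemia, proB ALL and B/T BAL. The eosinophil, basophil and mast cell list passed camera (adjusted p = 9.59e-10; adjusted p = 0.631 with an estimated correlation), and 4 of its 14 genes (Prg2, Prg3, Epx and Alox15) were lower when adjusted over the list alone. On the mixed lineage array 6 genes of this list were at least 2-fold higher and 7 at least 2-fold lower, with a median of -0.69 that turned to 0.20 with a filter at the 75th percentile and was -0.42 with signals below the floor raised to it. Ppbp, a platelet chemokine, had 16168 in normal marrow and between 244 and 351 in the leukemias, and the megakaryocyte list had medians of -1.71, -2.65 and -2.56 (camera adjusted p = 2.53e-16; adjusted p = 0.218 with an estimated correlation). Of its 16 genes, 6 were lower when adjusted over the list alone. Macrophage genes had medians of -2.01, -1.52 and -2.33 (camera adjusted p = 6.83e-11; adjusted p = 0.218 with an estimated correlation), with 0 of 15 genes lower when adjusted over the list alone. Mrc1, the mannose receptor of macrophages, had 3870 in normal marrow and 480, 1509 and 250 in the leukemias.

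The early B-cell list was lower by its median in all 3 leukemias, the proB ALL included, though not gene by gene. Of its 24 genes, 18 were at least 2-fold lower and 0 higher in mixed lineage leukemia, 16 lower and 3 higher in proB ALL, and 13 lower and 7 higher in B/T BAL, with 8 lower in all 3. Vpreb1 and Igll1, which encode the surrogate light chain of the pre-B-cell receptor, had signals of 11111 and 4111 in normal marrow and, by these probe sets, lay below the floor on each leukemia array, at least 58.9-fold and at least 21.8-fold lower. The other probe set of Igll1 had 503 in normal marrow and 305, 31.2 and 244 in mixed lineage leukemia, proB ALL and B/T BAL. Ebf1, a transcription factor of early B cells, had 697 in normal marrow and 138, 128 and 117 in mixed lineage leukemia, proB ALL and B/T BAL. Pax5 was below the floor on all 4 arrays, with 185 in normal marrow. The early B-cell list had medians of -1.64, -1.40 and -1.81 and passed camera (adjusted p = 2.2e-09; adjusted p = 0.218 with an estimated correlation), and 4 of its 24 genes (Vpreb1, Vpreb3, Igll1 and Blnk) were lower when adjusted over the list alone. Mature B-cell genes had medians of -0.15, 0.02 and -1.84 (camera adjusted p = 0.000431; adjusted p = 0.631 with an estimated correlation), and the middle value, that of proB ALL, was -0.07 under quantile normalization and -0.06 under scaling to the 75th percentile. Plasma cell genes had medians of -1.19, -0.70 and -0.64, the first of which was -0.65 with signals below the floor raised to it, and missed the threshold in camera (adjusted p = 0.0703).

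Stem and progenitor genes, cell cycle genes and interferon response genes were lower as lists as well. The stem and progenitor list had medians of -0.45, -1.34 and -1.83 in mixed lineage leukemia, proB ALL and B/T BAL (camera adjusted p = 2.42e-06; adjusted p = 0.595 with an estimated correlation). Tal1, a factor of blood stem cells that red cell precursors also express, was the 1 gene of its 21 that was lower when adjusted over the list alone, with 17694 in normal marrow and 749, 145 and 214 in the leukemias. Cd34, a surface protein of progenitors, had 1641 in normal marrow and 244, 175 and 252 in the leukemias, and Kit, a stem cell receptor, had 2413 against 2061, 1366 and 201. S-phase genes had medians of -0.75, -0.61 and -0.04 (camera adjusted p = 0.000134; adjusted p = 0.631 with an estimated correlation), and G2/M genes had -0.52, -1.13 and -0.45 (camera adjusted p = 3.13e-06; adjusted p = 0.631 with an estimated correlation). Mki67, a marker of dividing cells, had 28986 in normal marrow and 21304, 19940 and 22166 in the leukemias. Interferon response genes had medians of -0.79, -0.55 and -2.01 (camera adjusted p = 1.72e-07; adjusted p = 0.631 with an estimated correlation), and Rsad2, an antiviral protein, had 45401 in normal marrow and 1038, 1527 and 820 in the leukemias, lower when adjusted over the list alone. In the S-phase and G2/M lists 0 genes passed when adjusted over the list alone.

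Genes higher in all 3 leukemias were fewer and less far apart. Tagln2, an actin-binding protein, had a signal of 1770 in normal marrow and 15819, 15464 and 10863 in mixed lineage leukemia, proB ALL and B/T BAL, but without probe sets marked for cross-hybridisation it had a log2 difference of -0.48. Egr1, an immediate-early transcription factor, had 766 in normal marrow and 4516, 3528 and 5763 in the leukemias. Rpl37, a ribosomal protein, had 1307 against 5319, 8416 and 17176, though it was measured only by a probe set marked for cross-hybridisation. Serpinb6e, also measured only by such a probe set, was below the floor in normal marrow and had 1520, 583 and 1176 in the leukemias. Polr3k, an RNA polymerase subunit, had 576 in normal marrow against 2686, 5660 and 4690, but another of its probe sets had 1814 against 1441, 2031 and 1448, and with the mean over probe sets its log2 difference was 0.49. The immediate-early and heat shock list passed camera as higher (adjusted p = 0.0334; adjusted p = 0.631 with an estimated correlation), with medians of 1.65, -0.16 and 0.38. Cytosolic ribosomal protein genes were higher, with medians of 0.56, 0.15 and 1.09 (camera adjusted p = 1.35e-06; adjusted p = 0.631 with an estimated correlation). The T-cell list also passed camera as higher (adjusted p = 2.62e-06; adjusted p = 0.631 with an estimated correlation), with medians of -0.45, 1.90 and 4.35. In each of these 3 lists 0 genes passed when adjusted over the list alone.

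No single gene passed limma's adjusted threshold between leukemia and normal marrow: 0 genes were higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.0702, shared by 17 genes that were all lower. At an unadjusted p under 0.05 there were 44 higher and 369 lower genes, 413 in all. With robust eBayes 23 genes passed as lower, and with a pseudocount at the 50th percentile 15 did. Without proB ALL 4 genes were higher and 67 lower, without B/T BAL 4 were higher and 109 lower, and without mixed lineage leukemia 0 passed in either direction. At least 2-fold in the same direction in all 3 leukemias, 183 genes were higher and 624 lower. These 3 comparisons share the 1 normal array. In the simulated arrays, the 13812 unchanged genes of each draw gave 755 and 748 such genes on average. The simulation gave the normal array the spread fitted between the 3 leukemias, which need not hold for it. Over tested genes, Pearson's r was 0.827 to 0.850 between normal marrow and each leukemia, and 0.751, 0.790 and 0.873 among the leukemias. The simulated counts therefore do not settle how many of the 183 and 624 genes chance would give. Setting each of the other arrays apart from the remaining 3 gave 1767 genes at an unadjusted p under 0.05 for mixed lineage leukemia, 533 for proB ALL and 853 for B/T BAL. Camera passed 12 lists as lower and 3 as higher, and 0 lists with an estimated correlation. Without mixed lineage leukemia 5 lists were higher.

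**Figure D1:**
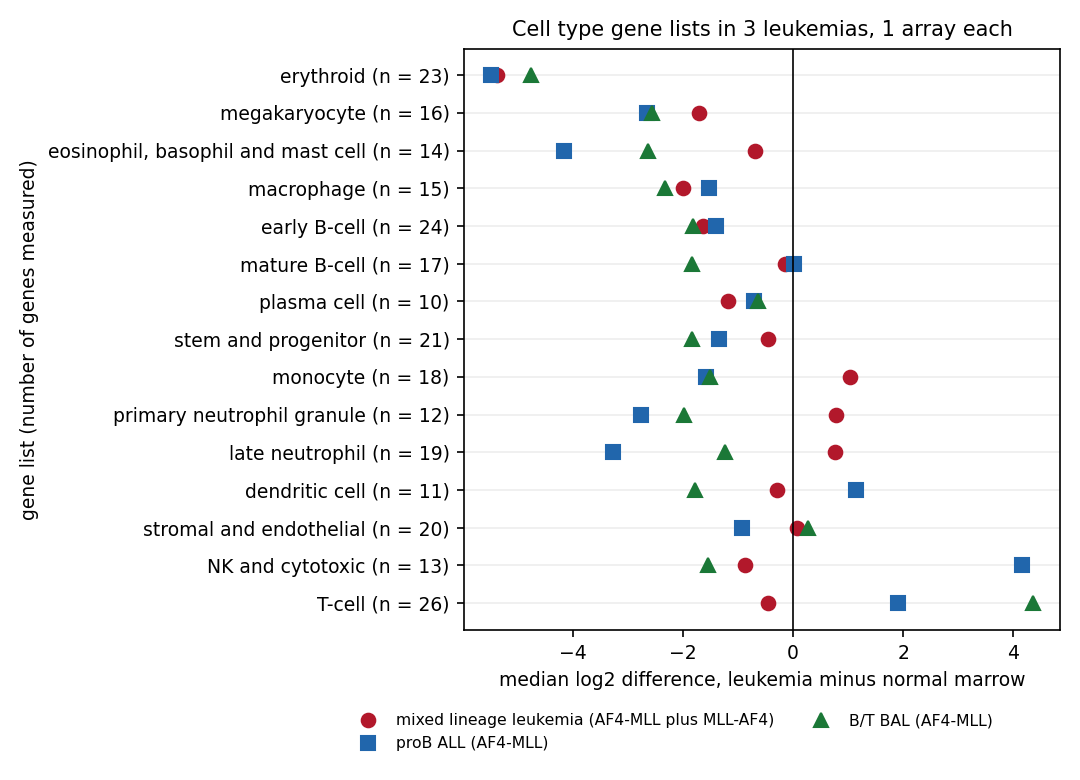
Median log2 difference between each leukemia and normal bone marrow (horizontal axis) for the 15 gene lists named for a cell type (vertical axis), with 1 symbol per leukemia array. Erythroid genes lie between -5.48 and -4.76 in all 3 leukemias, while NK and cytotoxic genes stand at 4.15 in proB ALL and T-cell genes at 4.35 in B/T BAL.

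The array labelled proB ALL carried high signals of natural killer (NK) and cytotoxic cell genes. All 13 measured genes of the NK and cytotoxic list were at least 2-fold higher than in normal marrow, with a median log2 difference of 4.15 (above 100% of matched random lists), against -0.87 in mixed lineage leukemia and -1.54 in B/T BAL. Gzmb, a granule protease of killer cells, had a signal of 26953 and lay below the floor on the other arrays, at least 143-fold lower. Gzmk, another granzyme, had 22046 against at most 347 elsewhere, and Klrk1, the receptor NKG2D, had 19005 against at most 521. Eomes, a transcription factor of NK cells and cytotoxic T cells, had 15148 against 641 in normal marrow, and Ncr1, an NK receptor, had 4694 against 251. T-cell genes had a median of 1.90, with Thy1 at 28959 and Cd3d at 12582 but Cd3e at 32, below the floor. Bcl2, an inhibitor of cell death, had 19896 against 1398 in normal marrow, and Il7r, the receptor of interleukin 7, had 13196 against 2486. Cd24a, a surface protein of B-cell precursors and other marrow cells, was among the 4 genes furthest below all other arrays, with 3017 against at least 31565. Rag1 and Dntt, which act in antigen receptor gene rearrangement, lay below the floor. Late neutrophil genes had a median of -3.27, primary neutrophil granule genes -2.77 and monocyte genes -1.58. In all, 1582 genes were at least 2-fold higher than in normal marrow and 2623 at least 2-fold lower.

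The B/T BAL array carried genes of immature T cells. T-cell genes had a median of 4.35 (above 100% of matched random lists), and 25 of 26 were at least 2-fold higher than in normal marrow. Cd3e and Cd3g, parts of the T-cell receptor complex, had signals of 11474 and 25806 against 372 and 632 in normal marrow, and Cd8a had 10607 against 307. Ptcra, which encodes the pre-T-cell receptor alpha chain, had 7093 and lay below the floor on the other arrays. Rag1 had 14988 against 1721 in normal marrow and Dntt had 11061 against 2913. Lef1, a factor of developing lymphocytes counted in the early B-cell list, had 16719 against 687. That list as a whole had a median of -1.81, with 13 of 24 genes at least 2-fold lower and 7 higher. Mature B-cell genes had a median of -1.84, with 14 of 17 at least 2-fold lower and 0 higher. NK and cytotoxic genes had a median of -1.54, late neutrophil genes -1.23, primary neutrophil granule genes -1.98 and monocyte genes -1.50. Against this, Gzma, another granzyme, had 52157 against 1556. Among the 8 genes furthest above all other arrays were Cym, a stomach protease, at 41625 against at most 549, Pdgfrb, a receptor of mesenchymal cells, at 30356 against at most 461, and Camk4, a calcium-dependent kinase of T cells and neurons, at 11053 by a probe set that lay below the floor on the other arrays. Stromal and endothelial genes had medians of 0.07, -0.92 and 0.27 in mixed lineage leukemia, proB ALL and B/T BAL (camera adjusted p = 0.717), the first of which was -0.04 under quantile normalization. On the B/T BAL array 6 of 20 were at least 2-fold higher and 4 at least 2-fold lower, and among the higher was Col1a2, a collagen chain, at 38648 against 2397. Fgl2 and Arsb were among the 4 genes furthest below all other arrays. In all, 2159 genes were at least 2-fold higher than in normal marrow and 2474 at least 2-fold lower.

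The mixed lineage array carried myeloid genes. Monocyte genes had a median of 1.04 and late neutrophil genes 0.76 (each above 100% of matched random lists), and primary neutrophil granule genes 0.79 (above 99.9%). At least 2-fold higher were 10 of 18 monocyte genes, 5 of 19 late neutrophil genes and 3 of 12 primary neutrophil granule genes. In these lists 0, 1 and 1 genes were at least 2-fold lower. Over all 14012 tested genes, 2630 were at least 2-fold higher. Vcan, an extracellular matrix protein made by monocytes, had a signal of 7714 and lay below the floor in normal marrow, and Fcnb, a protein of neutrophil precursors, had 29035 against 6243. F13a1, a coagulation factor of monocytes, had 39455 against 12879, Fn1 (fibronectin) had 43413 against 4677, and Itgam, a surface integrin of myeloid cells, had 4382 against 1262. Mpo, the main enzyme of primary granules, had 60520 against 43969. Il6, an inflammatory cytokine, had 1700 against at most 136 on the other arrays. Over the 3 leukemias the late neutrophil and primary neutrophil granule lists passed camera as lower (adjusted p = 0.000801 and 0.017; adjusted p = 0.74 and 0.631 with an estimated correlation), with 0 genes lower when adjusted over the list alone, and the monocyte list did not pass (adjusted p = 0.0703). T-cell genes had a median of -0.45 and NK and cytotoxic genes -0.87, and the NK and cytotoxic list did not pass camera (adjusted p = 0.372). Ribosome biogenesis and Myc-related genes had a median of -1.18 against normal marrow, while proB ALL had 0.94 and B/T BAL 1.03. With medians of opposite sign, this list did not pass camera over the 3 leukemias against normal marrow, which does not test the leukemias against one another. Myc, a transcription factor of cell growth, had 521 against 2774 in normal marrow. In all, 2630 genes were at least 2-fold higher than in normal marrow and 2126 at least 2-fold lower. Higher genes thus made up 55.3% of those at least 2-fold apart, and under quantile normalization 43.5%, with 1920 higher and 2489 lower. Under scaling to the 75th percentile they made up 64.4%, with 3259 higher and 1804 lower.

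**Figure D2:**
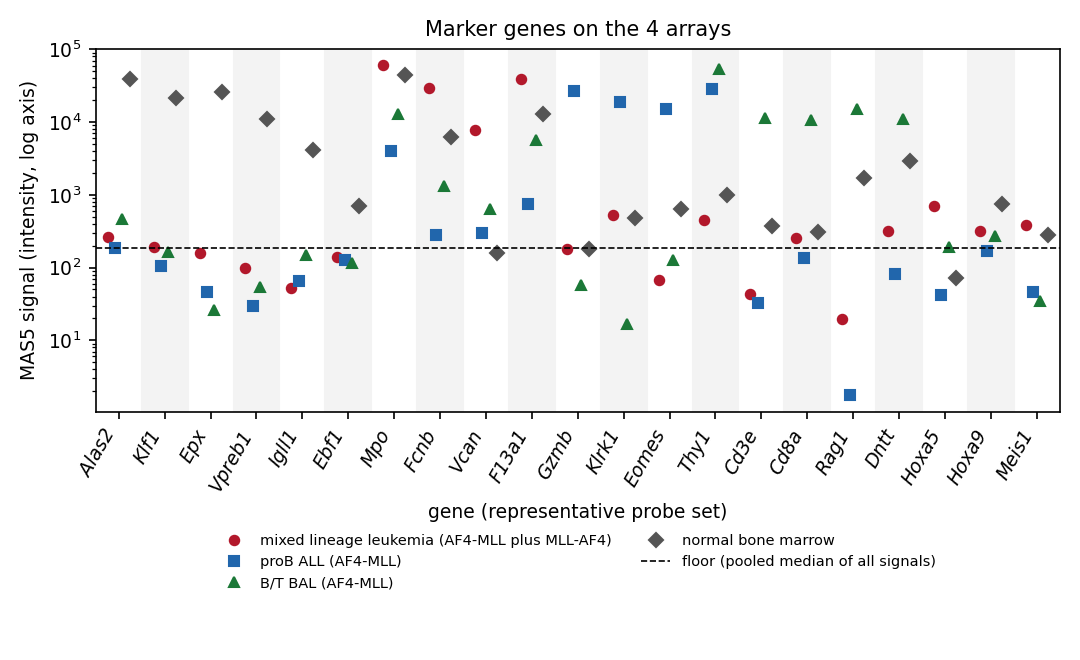
Signal (MAS5 intensity, log axis) of 21 marker genes (horizontal axis) on the 4 arrays, 1 symbol per array, with the floor of 189 as a dashed line. Alas2 stands at 39547 in normal marrow and at most 467 in the leukemias, Gzmb at 26953 in proB ALL, Cd3e at 11474 in B/T BAL and Vcan at 7714 in mixed lineage leukemia.

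On these arrays, with 1 for both fusions, the leukemia with AF4-MLL and MLL-AF4 differed from the AF4-MLL leukemias in myeloid and T-cell genes. Fusion and immunophenotype cannot be separated because each fusion state had its own immunophenotypes. Monocyte genes were higher than in the mean of the AF4-MLL leukemias by a median of 2.41 on the log2 scale, primary neutrophil granule genes by 2.98, late neutrophil genes by 2.85 and eosinophil, basophil and mast cell genes by 2.77. T-cell genes had a median of -3.25, NK and cytotoxic genes of -2.68 and ribosome biogenesis and Myc-related genes of -2.08. The NK and cytotoxic difference came from proB ALL alone. Against normal marrow that list had medians of 4.15 in proB ALL, -0.87 in mixed lineage leukemia and -1.54 in B/T BAL. By these medians mixed lineage leukemia was not lower than B/T BAL in NK and cytotoxic genes. Prom1, a surface protein of progenitors, had a log2 difference of 4.65 ± 0.67 (limma estimate ± SE), Vcan 3.98 ± 0.73 and Myc -3.64 ± 0.58. Lat, an adaptor of T-cell receptor signalling, lay below the floor in mixed lineage leukemia and had signals of 4436 in proB ALL and 26454 in B/T BAL. Adjusted over the list alone, 12 of 18 monocyte genes, 10 of 19 late neutrophil genes, 9 of 12 primary neutrophil granule genes, 7 of 14 eosinophil, basophil and mast cell genes, 3 of 21 stem and progenitor genes and 2 of 7 HOXA genes were higher, while 19 of 23 ribosome biogenesis and Myc-related genes, 12 of 26 T-cell genes and 1 of 13 NK and cytotoxic genes were lower. In the megakaryocyte and MLL-rearranged leukaemia lists 1 gene each was higher, and in the immediate-early and heat shock list 1 was higher and 1 lower. Camera, which was not planned for this comparison, passed 5 lists as higher, namely monocyte, late neutrophil, primary neutrophil granule, HOXA cluster (adjusted p = 0.00267) and eosinophil, basophil and mast cell genes. It passed 4 as lower, namely T-cell, NK and cytotoxic, ribosome biogenesis and Myc-related, and MLL and AF4 complex genes (adjusted p = 0.017 for the last), and 0 lists with an estimated correlation (adjusted p = 0.935 for each of them). The HOXA call rests on signals mostly below the floor in the AF4-MLL leukemias and goes with the higher lowest signals of the mixed lineage array. Over all genes, limma found 0 higher and 0 lower, with a smallest adjusted p of 0.151 and, at an unadjusted p under 0.05, 1726 higher and 767 lower genes. No setting with a test gave any gene in this comparison.

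Genes of the HOXA cluster, which MLL fusions are known to activate, were measured near the floor. Their median was 1.69 in mixed lineage leukemia, -0.44 in proB ALL and -0.24 in B/T BAL, at percentiles of 89.8, 25.1 and 22.7 of matched random lists (camera adjusted p = 0.702 against normal marrow), and 0.70, 0.00 and 0.00 with signals below the floor raised to it. Hoxa5 had a signal of 695 in mixed lineage leukemia and lay below the floor in normal marrow, at least 3.68-fold higher, but its other probe set was below the floor in each leukemia and had 202 in normal marrow. Hoxa9 had 320, 171 and 269 in mixed lineage leukemia, proB ALL and B/T BAL against 743 in normal marrow, and its other probe set had 513, 295 and 200 against 280. Meis1, a partner of HOXA proteins, had 385 in mixed lineage leukemia, 45.8 in proB ALL and 34.6 in B/T BAL against 282 in normal marrow. Another probe set of Meis1 had 25.3, 71.8 and 201 against 296. Kmt2a itself had 1660, 2869 and 4001 against 1160, and its other probe set had 453, 1419 and 1669 against 916, lower than normal marrow in mixed lineage leukemia. Aff1 had 5091, 2004 and 4263 against 4329. A probe set cannot tell a fusion transcript from the resident gene. Genes reported in MLL-rearranged leukaemia had medians of 0.40, -0.52 and -0.88, and 0.45, -0.27 and -0.29 with signals below the floor raised to it, with Satb1, a chromatin organiser of lymphocytes, at 5049, 8046 and 18916 against 2171. Genes of the MLL and AF4 complexes had medians of -0.39, 0.11 and 0.20, and neither list passed camera against normal marrow (adjusted p = 0.786 and 0.986). For the MLL and AF4 complexes the median and mean over the leukemias were -0.13 and -0.04, while camera's direction was up.

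More genes were at least 2-fold apart between mixed lineage leukemia and each AF4-MLL leukemia than between mixed lineage leukemia and normal marrow. Between mixed lineage leukemia and B/T BAL 3681 genes were at least 2-fold higher in mixed lineage leukemia and 2970 lower, and between mixed lineage leukemia and proB ALL 3829 were higher and 2196 lower. Between the proB ALL and the B/T BAL, both with AF4-MLL, 1466 genes were at least 2-fold higher in proB ALL and 2225 lower. Over tested genes, Pearson's r was 0.873 between proB ALL and B/T BAL, 0.790 between mixed lineage leukemia and proB ALL and 0.751 between mixed lineage leukemia and B/T BAL, against 0.842, 0.850 and 0.827 between mixed lineage leukemia, proB ALL and B/T BAL and normal marrow. These correlations run across genes, which are not independent replicates. An alternative chosen after seeing the data raised signals below the floor to the floor. With it 2313 genes were higher in mixed lineage leukemia than in proB ALL and 2007 lower. Against normal marrow 1531 were higher and 1816 lower, and against B/T BAL 2548 were higher and 2663 lower. Quantile normalization gave 3121 higher and 3103 lower against B/T BAL, and scaling to the 75th percentile gave 4329 higher and 2497 lower.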

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

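All tests of explanations in this part were chosen after the results were seen. In 5 gene lists 1 leukemia went opposite to both others against normal marrow, with all 3 medians at least 0.5 in size on the log2 scale. These were NK and cytotoxic genes in proB ALL (4.15) and, in mixed lineage leukemia, primary neutrophil granule genes (0.79), late neutrophil genes (0.76), monocyte genes (1.04) and ribosome biogenesis and Myc-related genes (-1.18). Each leukemia is 1 array, so no test with replicates was possible. The only test among leukemias was that of both fusions against AF4-MLL alone, given above, with 1 residual degree of freedom.

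Signals outside the gene comparisons also stood above normal marrow on the B/T BAL array. Its poly-A spike-in controls, bacterial RNAs added before labelling, had 4.10 times the mean signal of normal marrow, and its hybridization controls had 2.49 times. On the mixed lineage array these ratios were 0.902 and 1.97, and on the proB ALL array 0.482 and 0.804.

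The array labelled proB ALL showed high NK and cytotoxic genes and low early B-cell genes. The low early B-cell genes were not particular to it. That list had medians of -1.64 in mixed lineage leukemia, -1.40 in proB ALL and -1.81 in B/T BAL. An exchange of the proB ALL and B/T BAL labels would leave the B/T BAL array without a T-cell program, if proB leukemic cells lack one, but there the median of the 26 genes of the T-cell list was 4.35 (95% bootstrap interval over genes 3.85 to 4.82), which argues against it. B-lineage genes do not decide it, since on the same array 11 of them, picked by hand after the results were seen, had a median of -3.43 (-4.37 to -2.16) and all 24 genes of the fixed early B-cell list, some of which immature T cells share, had -1.81 (-2.89 to 0.55). NK or T cells among leukemic cells, a label exchanged with an outside sample, leukemic cells that express few B-lineage genes, and an NK-like program of the leukemic cells stay open, and none of them was tested. The cells were typed by flow cytometry but not sorted, and 1 mouse stands for this immunophenotype.

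Erythroid genes were lower on all 3 leukemia arrays. Scaling of the arrays does not account for this, since the erythroid median closest to 0 was -4.80 among 6 medians under quantile normalization and scaling to the 75th percentile. Even dilution of all resident marrow cells by leukemic cells would lower macrophage and erythroid genes alike, if leukemic cells expressed neither. The macrophage median lay above the erythroid median by 3.36 in mixed lineage leukemia, 3.96 in proB ALL and 2.43 in B/T BAL. The 95% bootstrap intervals over genes began at 1.95, 2.61 and 1.28. Leukemic cells that express some macrophage genes would also leave such a gap, so it cannot set even dilution aside. An uneven loss of resident cells, with red cell precursors lost further than macrophages, may account for the pattern. So might even dilution with such expression, or an unusual normal sample. With 1 normal array none of these was tested.

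The mixed lineage array had more genes higher than lower, by 504 against normal marrow and by 1633 against proB ALL. This is consistent with a higher background on that array: with signals below the floor raised to it, the excess was -285 against normal marrow and 306 against proB ALL. Real differences among dim genes would vanish in the same way, and the second fusion and the myeloid immunophenotype stay open, untested.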

How the results depend on the processing

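1 alternative, signals below the floor raised to it, was chosen after seeing the data; the others were planned. Of 1735 values recomputed under 17 alternatives, 1587 stayed the same and 105 moved. The moved values were 31 counts, 46 list medians and 28 margins of a named gene over the nearest other array. Counts moved by more than 1.5-fold or from 0, medians by more than the spread between leukemias, and margins by at least 1 on the log2 scale. Another 39 passed a threshold that they missed before, and 4, all single genes, changed direction. For genes and list medians, a change of direction was counted only where the first value was at least 1 in size. Smaller values that turned sign are not among the 4. The causes were not tested unless stated. Among 834 recomputed list medians, which include some of the moved values, 24 that started under 0.5 in size turned sign or became 0. A median that did so under several alternatives was counted each time. A larger one turned in 1 case, that of eosinophil, basophil and mast cell genes in mixed lineage leukemia, from -0.69 to 0.20 with a filter at the 75th percentile. The count of genes lower in leukemia, 0, became 15 with a pseudocount at the 50th percentile, 23 with robust eBayes and 0 to 109 when 1 leukemia was left out, and the count of higher genes, 0, became 0 to 4. The comparison of both fusions with AF4-MLL alone has no residual degrees of freedom without 1 leukemia, so it was not run. Gene lists ranged from 3 to 5 higher and 11 to 13 lower when 1 leukemia was left out, and lists passing camera became 0 higher and 0 lower with an estimated correlation. A pseudocount at the 50th percentile gave 1541 genes at least 2-fold higher in mixed lineage leukemia than in normal marrow and 1410 at least 2-fold lower in proB ALL than in B/T BAL. A filter at the 75th percentile tests fewer genes, and left 782 higher in mixed lineage leukemia, 1667 lower in proB ALL and 1431 higher in B/T BAL against normal marrow, 1408 higher in mixed lineage leukemia against proB ALL, 1742 against B/T BAL, and 1285 lower in proB ALL against B/T BAL; the HOXA cluster then had no gene left and no value. A 4-fold threshold counts fewer genes by construction: against normal marrow 675 higher and 590 lower in mixed lineage leukemia, 400 and 875 in proB ALL and 531 and 935 in B/T BAL; against proB ALL 1504 and 648, and against B/T BAL 1455 and 979, in mixed lineage leukemia; and against B/T BAL 458 and 538 in proB ALL. With signals below the floor raised to it, 1531 genes were higher in mixed lineage leukemia than in normal marrow and 2313 than in proB ALL. Hoxa5 turned to -0.19 with the mean over probe sets, which takes in its other probe set. Without probe sets marked _x_at or _s_at, Hoxa5 turned to -1.43 and Tagln2 to -0.48, because other probe sets then stood for these genes. Cd8a ranged from -0.58 without B/T BAL, the array that held its high signal, to 2.34 without proB ALL. The higher lowest signals of the mixed lineage array, whatever their cause, limit what can be said of genes near the floor.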

Other observations

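Metabolic, antigen presentation and control genes did not pass camera between leukemia and normal marrow. They did not pass between both fusions and AF4-MLL alone either, the only test among the leukemias. MHC class I genes had medians of -0.03, 1.01 and -0.31 in mixed lineage leukemia, proB ALL and B/T BAL against normal marrow, the first of which was 0.06 under quantile normalization, and Nlrc5, an activator of MHC class I genes, had signals of 557, 9742 and 307 against 1352. Dendritic cell genes had medians of -0.29, 1.15 and -1.78. Over the 3 leukemias their median was 0.04 and their mean -0.18, and camera's direction was down. Glycolysis genes had medians of 0.62, 0.11 and 0.56, with Pkm, a pyruvate kinase, at 19061, 14275 and 21341 against 7418 and Pfkm, a phosphofructokinase of muscle and red cells, at 109, 890 and 2015 against 2890. Oxidative phosphorylation genes had medians of 0.00, 0.01 and 0.49, the first of which was -0.16 under quantile normalization and 0.14 under scaling to the 75th percentile, and the middle value was -0.08 under the latter. Housekeeping genes had medians of 0.43, 0.17 and 0.09.

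BCL2 family genes had medians of 0.17, 0.25 and -0.20 and p53 target genes of 0.09, 0.20 (0.05 with signals below the floor raised to it) and 0.03, the last of which was close to 0 and below it under scaling to the 75th percentile. Bcl2l11, a death-promoting member, had 10681 in proB ALL beside the high Bcl2 there, against 2708 in normal marrow, and Bmf, another such member, had 4371 in B/T BAL against 682. Sex-linked genes had medians of 0.84, -0.04 and 0.10 over 3 genes, and the middle value was 1.04 under quantile normalization, while the first was 0.09 with signals below the floor raised to it. Camera gave adjusted p-values of 0.238 for MHC class I genes, 0.808 for dendritic cell genes, 0.147 for glycolysis genes, 0.116 for oxidative phosphorylation genes, 0.261 for housekeeping genes, 0.712 for BCL2 family genes, 0.558 for p53 target genes and 0.329 for sex-linked genes.

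Lower in the leukemia with both fusions were Cd163l1, a scavenger receptor of gamma delta T cells, and Trgv1, a variable segment of the T-cell receptor gamma locus. Each lay below the floor there. Cd163l1 had signals of 19681 in proB ALL and 13017 in B/T BAL, and Trgv1 had 6350 and 12864. Both were chosen after their values were seen, from many genes that limma ranked equally by adjusted p-value, and neither passed the adjusted threshold.

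The NK and cytotoxic genes of the array labelled proB ALL leave the question of which cells carried them. If leukemic cells did, sorted leukemic cells of that mouse would keep Gzmb, Klrk1 and Eomes and carry the AF4-MLL transcript, and if resident cells did, sorting would remove these genes. If the loss of erythroid genes came from displaced red cell precursors, counts of these cells by flow cytometry would fall with the signal of Alas2 across mice. Several mice of each fusion with the same immunophenotype would separate the second fusion from immunophenotype. None of this was tested here.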
